A study of Mus musculus with 55 samples.

How the data were processed

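RNA of 5 B lineage populations sorted from mouse bone marrow was measured on 2 oligonucleotide array sets that carry different probe sets. The deposited files are 1 table per array set with 1 intensity per probe set and array, 6584 probe sets on 28 arrays of the first set and 6595 on 27 arrays of the b set. The intensities were computed and deposited by the authors on a linear scale with negative values, which made up 19.6 to 27.8% of an array on the first set and 33.9 to 42.4% on the b set. How the authors extracted, labelled, scanned, summarised and scaled them, and with which software, is not given in the sources used here. Gene symbols were taken from the probe set tables provided with the arrays.

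Groups were read from the sample labels: population, sort number and array set. The 26 preparations were 6 of pre-BI cells (sorts 1, 2, 3, 8, 9 and 10) and 5 each of large pre-BII (1, 2, 8, 9 and 10), small pre-BII (1, 3, 8, 9 and 10), immature (1, 2, 8, 9 and 11) and mature B cells (1, 3, 8, 9 and 11). Before the data were examined, the samples, the design, the gene lists, the rule for named genes and a set of alternatives were fixed. Arrays with a second number in the title were to be averaged with the array of the same population and first number. The design was departed from once: on the first set, the second mature B array of sort 1 held the same 6584 values as mature B sort 11, so it was not averaged into sort 1 and was kept once, as sort 11.

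The 2% trimmed means of the arrays differed 5.6-fold on the first set and 4.23-fold on the b set, so by the fixed rule each table was quantile-normalised between arrays after removal of 110 control probe sets. Values under the 40th percentile of a table (87.6 and 6.89) were raised to it and log2 was taken. Probe sets above that floor in at least 5 of 26 preparations were tested, 5019 of the first set and 5210 of the b set, in 1 fit of all 26 preparations (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were the 4 consecutive ones, mature B against pre-BI, and a moderated F test over the 5 populations. "Rose", "fell" and "changed" are used for what passed.

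Gene lists were tested with camera at an inter-gene correlation of 0.01, on the brightest probe set of each gene, for 29 lists and the 4 consecutive comparisons, with adjustment over all 116 tests. Camera with an estimated correlation was run beside it and called 19 tests where the preset correlation called 29. Fry, which tests a list on its own and not against other genes, was also run, and no call was taken from it. Counts adjusted over the list alone use the Benjamini-Hochberg adjustment within that list.

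Signal over background was judged from the negative values. A noise limit of 2 robust standard deviations, 251 on the first set and 319 on the b set, was exceeded by 40% and 20.1% of values. Because the main floor lies far under this limit on the b set, folds and log2 differences of single genes in the text are between means of values raised to the noise limit, while adjusted p-values come from the limma fit. Raising values to the limit removes the spread under it, so these SEs are small for a population that lies there. A gene with several probe sets is given by the one the rule for named genes takes in that comparison; another probe set of Vav1, Myb, Cnp, Slc16a1 and Cr2 had the opposite or no difference, without passing, in a comparison where the named one passed. A bound is given where no preparation of the dimmer population exceeded the limit, and no fold where the bound would be under 1 or both populations lay under it. The noise limit was chosen after the values had been seen.

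Genes were named by the fixed rule. It takes the 4 genes of the sort gates whatever their result. It takes the 8 largest rises and falls per comparison among probe sets with 1 symbol, an adjusted p under 0.05, an at least 2-fold difference and no overlap between preparations. It takes up to 4 passing members of each called list and 2 of each other list described, and the 2 brightest members of lists of other cell types. Socs1 and a few list members were named outside it, after their values had been seen.

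The pairing of sort numbers across populations comes from the labels, which do not say that equal numbers share a day or animals. Deviations from population means were therefore correlated between preparations of equal number. Numbers paired for large pre-BII and pre-BI (r from 0.11 to 0.3 in 5 pairs), immature and small pre-BII (0.14 to 0.25 in 3) and mature and immature cells (0.12 to 0.21 in 4). They were not taken to pair where not every r exceeded 0.1. This held for small and large pre-BII (0.0035 to 0.25, 1 of 4 over 0.1) and for mature and pre-BI cells (0.059 to 0.24, 3 of 4 over 0.1). Every r was positive there too, so a pairing is not excluded. Sort number was kept out of the main design, as fixed, and run as a replicate block beside it.

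The procedure was tested on simulated data, with differences added to shuffled deviations in 5 simulations. Of 2-fold differences 15.2 to 20% were recovered and of 8-fold ones 56 to 65.2%; among bright probe sets 39.2 to 57.4% and 100%. The share of false calls was 4.86% or less in 4 comparisons and 7.73% in large pre-BII against pre-BI, above the nominal 5%. A list shifted by 0.5 on the log2 scale was called in 4 of 5 simulations for large pre-BII against pre-BI and in 5 of 5 for the others. Other lists were called in 3, 2, 1 and 4 of 135 tests for the consecutive comparisons and in 8 for mature B against pre-BI. Beside 4 or 5 true calls per comparison, these put the share of false list calls above the nominal 5%. Adjustment in these simulations was over the 29 lists of 1 comparison, not over 116 tests.

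Alternatives comprised other scalings, floors, transforms and filters, the blocks, fits of 2 populations or 1 table, other treatments of repeat arrays and leaving out each preparation in turn. After the data had been seen, 7 more were added: the noise limit as the floor, the batch of sorts as a block, each batch alone, 2 other treatments of the identical array, and leaving out the 2 preparations of highest Gapdh ratio. Probe sets without a symbol were tested but are not named here.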

Results

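Transcript levels were measured in 5 populations of B lineage cells sorted from mouse bone marrow, on 2 oligonucleotide array designs that carried different probe sets, here called the first set and the b set. Pre-BI cells were sorted as B220+ c-kit+, pre-BII cells as B220+ CD25+ cells without surface immunoglobulin and divided into large and small cells, immature B cells as B220low cells with surface IgM, and mature B cells as B220high cells with surface IgM. The 55 arrays came from 26 preparations, each hybridised to both sets: 6 of pre-BI cells and 5 of each other population, numbered by sort. An array titled as a second mature B array of sort 1 on the first set was identical, in all 6584 values, to that of mature B sort 11. They were taken as 1 array, kept as sort 11, which left 54 arrays. The labels do not say which of the 2 titles is right. An 18S ribosomal RNA control read 28 on this array, against 3741 to 14192 on the other first-set arrays of sorts 1 to 3. This argues against the title of sort 1. The labels do not say whether preparations came from separate animals, so p-values measure only the spread between these preparations, which may be technical. The number of arrays limits the precision of every value below.

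Of 13069 probe sets other than controls, 7542 had 1 gene symbol, 224 had several and 5303 had none. After removal of dim ones 10229 were tested, of which 5992 had 1 symbol and stood for 5027 genes. Levels are normalised intensities. Folds are between population means, with values under the noise limit of the set (251 on the first set, 319 on the b set) raised to it, and are given as "at least" where no preparation of the dimmer population exceeded the limit. The noise limit was chosen after the values had been seen. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over all tested probe sets of a comparison.

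Across the 5 populations 1524 probe sets (14.9%) varied by the moderated F test. The population with the highest mean was large pre-BII for 377 of them, mature B for 340, pre-BI for 323, immature B for 268 and small pre-BII for 216.

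Transcripts of the genes named by the sort were examined first. Ptprc, which encodes the B220 antigen, averaged 2860 in pre-BI and 2720 in large pre-BII, rose 1.63-fold to 4430 in small pre-BII (adjusted p = 0.00318), rose 1.87-fold to 8280 in immature cells (adjusted p = 0.000463) and stood at 9170 in mature cells (adjusted p = 0.94 against immature). Kit, the receptor that marks the pre-BI gate, averaged 277 in pre-BI cells, where 2 of 6 preparations exceeded the noise limit, and no preparation of another population did. Il2ra, which encodes CD25, exceeded the limit in 1 of 5 small pre-BII preparations by one of its probe sets and in no preparation by the other, so no CD25 difference was measurable. Ighm, the mu heavy chain gene, was bright throughout by one probe set (9950 in pre-BI, 12600 in large pre-BII, 14100 in small pre-BII, 14200 in immature and 12800 in mature cells) and changed in no comparison.

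**Figure D1:**
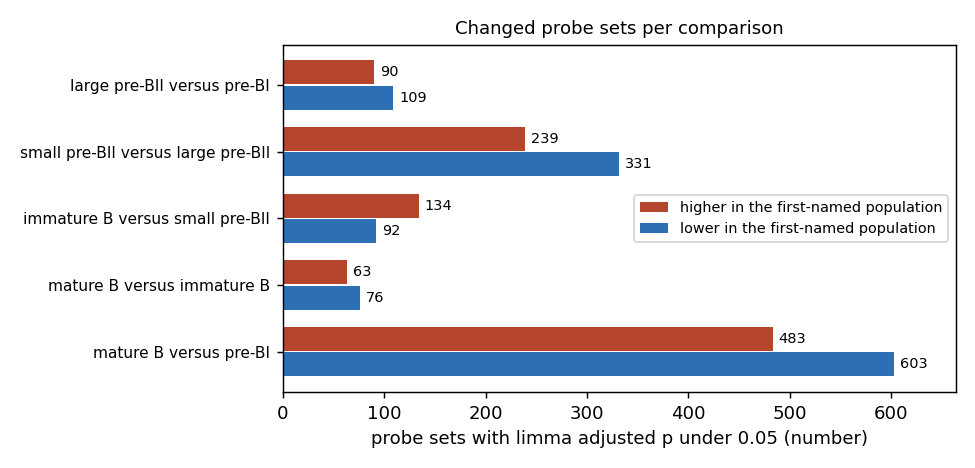
Number of probe sets (horizontal axis) with a limma adjusted p under 0.05 in each of the 5 comparisons (vertical axis), split into those higher and those lower in the first-named population. Among consecutive populations the step from large to small pre-BII cells had the most, 239 higher and 331 lower.

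Large pre-BII cells were compared with pre-BI cells, the preceding stage, on 5 and 6 preparations. Dntt, the terminal transferase that adds untemplated nucleotides at heavy chain joints, fell 22.5-fold (log2 difference −4.49 ± 0.12 SE, adjusted p = 0.00022). The surrogate light chain genes fell as well, Igll1 5.93-fold (−2.57 ± 0.52, adjusted p = 0.025) and Vpreb1 6.12-fold (−2.61 ± 0.31, adjusted p = 0.0487). Myl4, a myosin light chain gene, rose 7.5-fold (2.91 ± 0.23, adjusted p = 2.93e-07) and Irf4, a transcription factor of light chain gene activation, rose 4.23-fold (2.08 ± 0.32, adjusted p = 0.00176). Among mitotic genes 7 of 35 rose, Prc1 (2.43-fold) and Top2a (2.85-fold) among them. In all, 199 probe sets changed, 90 higher and 109 lower.

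The other leading rises were Fcrla, an Fc receptor-like gene of B cells (5.36-fold), Cdkn3 (3.75-fold), Emid1 (3.53-fold), Ube2c (3.49-fold) and Tirap, an adaptor of Toll-like receptors (2.39-fold). Cd2 also rose (adjusted p = 5.28e-05), from 15.3 to 289 in level, with 2 of 5 large pre-BII preparations above the noise limit and therefore no fold. Among the leading falls were Mgst2 (11.7-fold), Gbp7 (7.07-fold), Frmd6 (at least 5.16-fold), Eng, a TGF-beta coreceptor (at least 3.33-fold), and Itm2c (at least 1.26-fold). Thy1 and Chrnb1 also fell, from levels of 263 and 235, with 2 of 6 and 1 of 6 pre-BI preparations above the limit and therefore no fold.

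Of the surrogate light chain and early progenitor list, 4 of 20 tested genes fell and none rose (5 adjusted over the list alone): Dntt, Igll1, Vpreb1 and Lef1 (at least 2.24-fold). The list fell by camera (adjusted p = 0.00221, and adjusted p = 0.0116 with an estimated correlation). Of the G2 and mitosis list 7 of 35 rose (27 adjusted over the list alone; adjusted p = 2.8e-23, and 6.83e-05 with an estimated correlation), and the median of its genes was 1.02 on the log2 scale. The DNA replication list did not move (median 0.17, adjusted p = 0.336), with 0 of 35 genes changed (1 higher and 1 lower adjusted over the list alone). Of the list of CDK inhibitors and anti-proliferative genes 3 of 17 rose (6 adjusted over the list alone; adjusted p = 2.88e-05, and 0.0122 with an estimated correlation). These were Ccng2, an unconventional cyclin (2.16-fold), Klf2, a factor of quiescent lymphocytes (3.37-fold), and Cdkn2d, an inhibitor of Cdk4 and Cdk6 (3.09-fold). Of the G1 cyclin list Ccnd2 fell at least 3.04-fold and Rb1 rose 2.34-fold, and the list as a whole did not shift (adjusted p = 0.827), with a median of 0.07 against a mean of −0.14.

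The ribosome biogenesis and Myc-associated list fell, with 3 of 28 genes lower (5 adjusted over the list alone; adjusted p = 4.19e-05, and 0.000457 with an estimated correlation): Nme2 (1.65-fold), Ldha (2.06-fold) and Fbl (1.94-fold). Ldha was also the single member of the glycolysis list to fall (1 of 11, and 3 adjusted over the list alone; adjusted p = 0.00221, and 0.033 with an estimated correlation). A rise of the histone list (2 of 15, and 4 adjusted over the list alone; adjusted p = 0.00701) was lost, at adjusted p = 0.0958 with an estimated correlation. Its risen members were H2ax (2.34-fold) and Cenpa (2-fold), which are variants and not core replication histones. A fall of the ribosomal protein list (1 of 43, Rpl12; 1 adjusted over the list alone; median −0.16, adjusted p = 0.0136) was also lost, at adjusted p = 0.31 with an estimated correlation, and its median was 0.03 in the values as deposited. Blk (2.57-fold) and Syk (2.02-fold), kinases of receptor signalling, rose, but their list did not shift (2 of 20 higher and 1 lower, 4 and 3 adjusted over the list alone; adjusted p = 0.569, with a median of −0.01 and a mean of 0.04). Nfkbia rose 2.9-fold. H2-Aa, an MHC class II alpha chain gene, rose 3.99-fold by its brightest probe set, although pre-BI sort 10 had a level of 2300 where the other pre-BI preparations had 208 to 899. Gzma, a granzyme listed among T and NK cell genes, fell 3.38-fold.

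An 18S ribosomal RNA control separated sorts 1 to 3 from sorts 8 to 11, so each comparison was repeated with that batch as a block and within each batch. For large pre-BII against pre-BI cells 213 probe sets changed with the block, 8 within sorts 1 to 3 and 75 within sorts 8 to 11. Of the 75 called within sorts 8 to 11, 85.3% went the same way within sorts 1 to 3, against 53.8% of all tested probe sets. List medians with the block, within sorts 1 to 3 and within sorts 8 to 11 were −0.52, −0.41 and −0.61 for early progenitor genes, 0.98, 1.12 and 0.96 for G2 and mitosis, 0.48, 0.37 and 0.56 for CDK inhibitors, −0.40, −0.46 and −0.50 for ribosome biogenesis, −0.69, −0.22 and −1.0 for glycolysis, 0.47, 0.31 and 0.60 for histones, and −0.15, −0.16 and −0.22 for ribosomal proteins. The calls of glycolysis (adjusted p = 0.226) and ribosomal proteins (0.12) were not reached within sorts 1 to 3. With values raised to the noise limit these 7 medians were −0.31, 0.99, 0.26, −0.57, −0.23, 0.53 and −0.20. Sort numbers paired the preparations of these populations, and 328 probe sets changed with sort number as a replicate block. The count was 48 in the values as deposited, 129 with a floor at the 25th percentile and 302 with one at the 60th. Leaving out single preparations ended the call of Vpreb1 in 22 of 26 fits (adjusted p up to 0.148), Rpl12 in 21 (0.108), Igll1 in 5 (0.1, without large pre-BII sort 2), Lef1 in 5 (0.13) and Fbl in 4 (0.1), and those of Nme2 (0.0512, without large pre-BII sort 10) and Cenpa (0.0531, without large pre-BII sort 8) in 1 each. It ended that of the ribosomal protein list in 2 (0.119, without large pre-BII sort 9).

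Small pre-BII cells were compared with large pre-BII cells, sorted with the same surface markers and separated by size, on 5 preparations each. Proliferation genes fell, while a lambda light chain gene and a recombinase gene rose. Prc1, a regulator of cytokinesis, fell at least 12.7-fold (log2 difference −3.66 ± 0.08 SE, adjusted p = 6.89e-15), Top2a at least 12.2-fold (−3.60 ± 0.26, adjusted p = 7.36e-12) and Mki67, which encodes the proliferation antigen Ki-67, 7.77-fold (−2.96 ± 0.24, adjusted p = 9.97e-10). Iglc1, a lambda constant region gene, rose 16.5-fold (4.05 ± 0.23, adjusted p = 7.36e-12) and Rag1, a subunit of the V(D)J recombinase, rose 4.35-fold (2.12 ± 0.40, adjusted p = 7.56e-05). In all 570 probe sets changed, 239 higher and 331 lower.

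Of the G2 and mitosis list 32 of 35 genes fell (33 adjusted over the list alone; adjusted p = 1.65e-60, and 9.76e-08 with an estimated correlation). Of the DNA replication list 27 of 35 fell (31 adjusted over the list alone; adjusted p = 1.67e-32, and 2.59e-06 with an estimated correlation), led by Tk1 (at least 4.47-fold), Mcm3 (3.49-fold), Rrm1, the large subunit of ribonucleotide reductase (7.32-fold), and Slbp, the histone stem-loop binding protein gene (4.54-fold). Of the G1 cyclin list 4 of 11 fell (5 adjusted over the list alone; adjusted p = 6.11e-05, and 0.00127 with an estimated correlation): Rbl1 (4.66-fold), Ccne1 (at least 2.18-fold), Cdk2 (3-fold) and Ccnd3 (2.17-fold, adjusted p = 0.0488). The histone list fell (4 of 15, and 4 adjusted over the list alone; adjusted p = 0.000789, and 0.0482 with an estimated correlation), and its passing members were the variant genes H2ax (7.09-fold), H2az2 (3.39-fold), Cenpa (3.47-fold) and H2az1 (3.13-fold). Other leading falls were Hmmr (at least 3.62-fold), Melk (at least 1.83-fold), Nusap1, a spindle protein gene (19.9-fold), Actn4 (at least 3.2-fold) and Rad54l, of homologous recombination (at least 2.89-fold). The list of CDK inhibitors and anti-proliferative genes did not shift (adjusted p = 0.422). It had 2 rises, Btg2 (2.84-fold) and Btg1, and 2 falls, Cdkn2c, an inhibitor of Cdk4 and Cdk6 (6.03-fold), and Cdkn2d, with 4 higher and 2 lower adjusted over the list alone. Btg1 and Cdkn2d are named after their values were seen.

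Among the other leading rises were Reln, an extracellular glycoprotein best known from the brain (at least 7.6-fold), Evl, an actin regulator (7.22-fold), Cd2 (4.99-fold), Pim2, a survival kinase (at least 4.38-fold), and Prm1, a sperm protamine gene (at least 3.71-fold). Capg and Pgr also rose, to levels of 223 and 138 that 1 preparation each had above the noise limit. The immunoglobulin list rose, with Iglc1 the 1 member that passed (1 of 12, with 10 positive and a median of 0.64, and 1 adjusted over the list alone; adjusted p = 0.0342), and this call was lost, at adjusted p = 0.0888 with an estimated correlation. Of the V(D)J recombination list Rag1 rose, while Hmgb1 and Hmgb2, chromatin proteins that also assist RAG cleavage, fell, Hmgb1 1.73-fold; the list did not shift (adjusted p = 0.967), with a median of 0.36 against a mean of −0.13. Among early progenitor genes Ly6d rose 4.03-fold and Myb 2.11-fold, and that list did not shift (2 higher and 1 lower of 20, 2 and 2 adjusted over the list alone; adjusted p = 0.827).

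The receptor signalling list rose (5 of 20, and 8 adjusted over the list alone; adjusted p = 0.00107, and 0.0439 with an estimated correlation), with Prkcd (1.86-fold), the immunoglobulin-associated chains Cd79b (1.95-fold) and Cd79a (2.75-fold), and Vav1 (1.57-fold). The list of mature B cell surface and survival genes rose (6 of 23, and 8 adjusted over the list alone; adjusted p = 0.000736, and 0.0237 with an estimated correlation), with Cd1d1 (2.84-fold), Cd55 (at least 1.42-fold), Il4ra (at least 1.6-fold) and S1pr1, the receptor for sphingosine phosphate (2.28-fold). Of the MHC class II list Ctss rose 3.28-fold and Cd74, the invariant chain, 2.89-fold, while the list did not shift (3 of 10, and 3 higher and 1 lower adjusted over the list alone; adjusted p = 0.139). Of the apoptosis list 3 of 20 rose (4 adjusted over the list alone; adjusted p = 0.0712), among them Birc3 (4.83-fold) and Mcl1 (2.48-fold).

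With the batch as a block 637 probe sets changed between small and large pre-BII cells, 117 within sorts 1 to 3 and 353 within sorts 8 to 11. Of these 353, 94.1% went the same way within sorts 1 to 3, against 58.2% of all tested probe sets. List medians with the block, within sorts 1 to 3 and within sorts 8 to 11 were −2.87, −3.12 and −2.64 for G2 and mitosis, −2.0, −1.93 and −1.84 for DNA replication, −1.08, −0.78 and −0.89 for G1 cyclins, −0.19, −0.38 and −0.18 for histones, 0.47, 0.60 and 0.57 for receptor signalling, 0.63, 0.77 and 0.62 for mature B cell genes, and 0.64, 0.46 and 0.53 for immunoglobulin genes. The immunoglobulin call was not reached within either batch (adjusted p = 0.0507 and 0.156). With values raised to the noise limit these 7 medians were −2.55, −1.19, −0.70, −0.84, 0.39, 0.15 and 0.47. In the values as deposited 201 probe sets changed, 42 higher and 159 lower, so the share of rises fell from 41.9% to 20.9%. That share was 48.7% with trimmed-mean scaling (288 higher and 303 lower) and 33.8% with 75th-percentile scaling (168 and 329). The balance of rises and falls therefore depends on the scaling. Leaving out single preparations ended the call of Ccnd3 in 21 of 26 fits (adjusted p up to 0.168), of Vav1 in 3 (0.101), of the immunoglobulin list in 3 (0.127, without large pre-BII sort 2) and of Myb in 1 (0.0509, without small pre-BII sort 9).

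**Figure D2:**
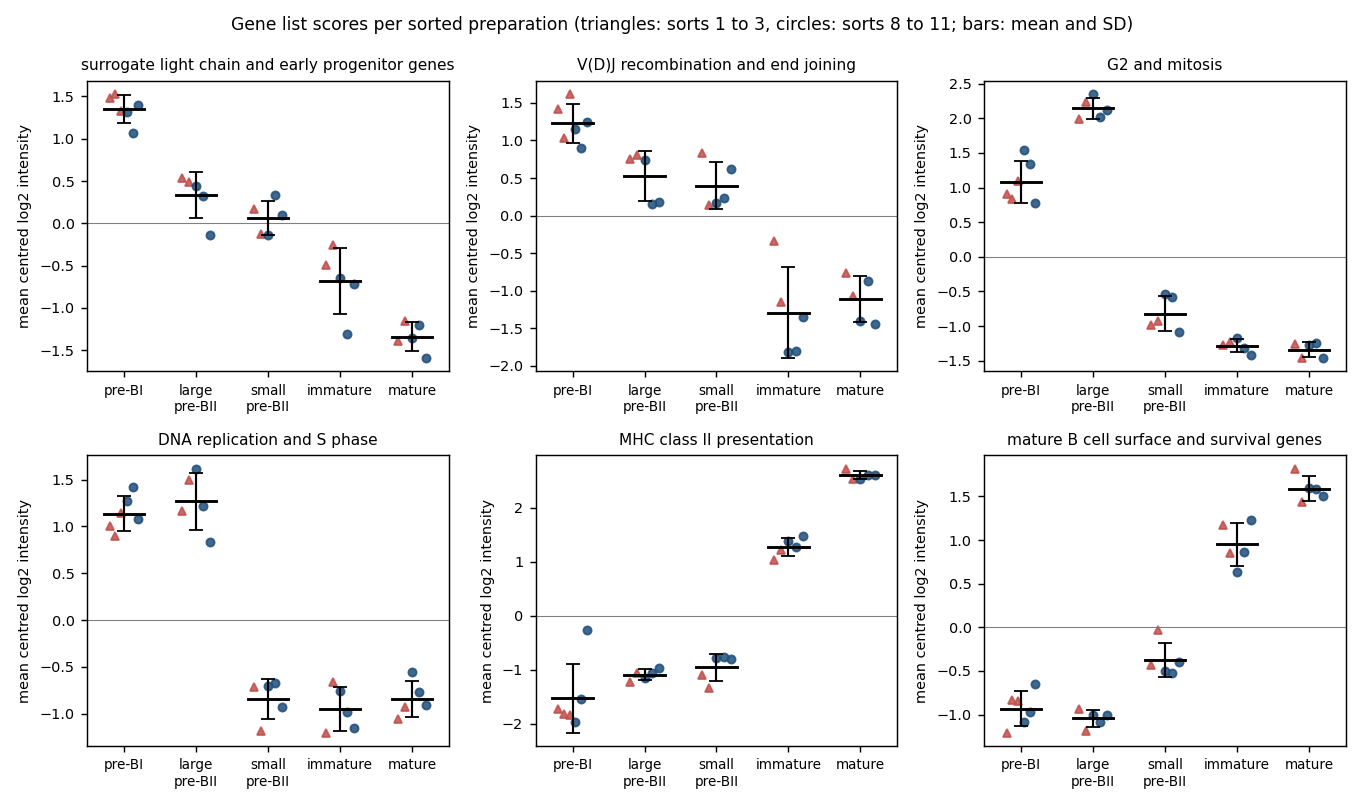
Score of 6 gene lists in each of the 26 preparations: the vertical axis is the mean over a list's genes of log2 intensity centred on each gene's mean, the horizontal axis the 5 populations. Triangles are preparations of sorts 1 to 3, circles those of sorts 8 to 11, and bars are means with SD. G2 and mitosis genes lie highest in large pre-BII cells and MHC class II genes in mature B cells, and pre-BI sort 10 lies apart from the other pre-BI preparations for MHC class II, at −0.27 against −1.97 to −1.53. Scores use values raised to the main floor, which lies under the noise limit, so genes under the limit also move them.

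Immature B cells were compared with small pre-BII cells on 5 preparations each. Genes of the B cell surface and of antigen presentation rose and the recombinase genes fell. Ms4a1, which encodes CD20, rose 21.6-fold by one probe set (log2 difference 4.43 ± 0.26 SE, adjusted p = 2.45e-10) and 6.34-fold by the other (adjusted p = 8.27e-08). H2-Eb1, an MHC class II beta chain gene, rose at least 13.7-fold (3.78 ± 0.16, adjusted p = 8.25e-06), and Ccnd2 at least 8.23-fold (3.04 ± 0.19, adjusted p = 3.65e-11). Rag1 fell at least 19.2-fold (−4.26 ± 0.28, adjusted p = 3.65e-11) and Rag2 at least 2.13-fold (adjusted p = 0.00409). In all 226 probe sets changed, 134 higher and 92 lower.

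The other leading rises were H2-DMa (at least 2.52-fold), H2-Ab1 (8.21-fold), Ctsh, a lysosomal protease gene (8.9-fold), Fes (at least 1.24-fold) and Cxcr5, the receptor for entry into B cell follicles, from 10.7 to 251 in level with 2 of 5 immature preparations above the noise limit. The other leading falls were Reln (7.4-fold), Ptgr1 (9.74-fold), Prm1 (at least 3.71-fold) and Slc16a1, a lactate transporter gene (at least 2.93-fold). Cnp, H2-Q1 and Aqp4 also fell, but both populations lay under the noise limit.

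Of the MHC class II list 6 of 10 genes rose (8 adjusted over the list alone; adjusted p = 1.5e-13, and 8.89e-05 with an estimated correlation), among them H2-DMa, H2-Aa (7.28-fold), H2-DMb1 (2.95-fold) and Cd74 (4.55-fold). Of the mature B cell list 9 of 23 rose (12 higher and 1 lower adjusted over the list alone; adjusted p = 1.96e-14, and 2.7e-05 with an estimated correlation), led by Ms4a1, Fcer2a, the low affinity IgE receptor (at least 5.88-fold), Cd83 (8.73-fold) and Cd40 (at least 1.46-fold). Of the receptor signalling list Ptpn6, a phosphatase (4.38-fold), and Cd22, an inhibitory coreceptor (8.63-fold), rose (2 of 20, and 2 adjusted over the list alone; adjusted p = 0.00203), a call that was lost at adjusted p = 0.0527 with an estimated correlation. The MHC class I list rose, with Psmb8 the 1 member that passed (1.74-fold; 1 of 13, and 2 adjusted over the list alone; adjusted p = 0.0194), and was lost at adjusted p = 0.122 with an estimated correlation.

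Of the V(D)J recombination list 4 of 9 genes fell (5 adjusted over the list alone; adjusted p = 9.51e-08, and 0.000363 with an estimated correlation): Rag1, Hmgb1 (1.81-fold), Hmgb2 (2.5-fold) and Rag2. The early progenitor list fell (1 of 20, and 3 adjusted over the list alone; adjusted p = 0.002, and 0.0108 with an estimated correlation), and the member that passed was Myb, a transcription factor of haematopoietic progenitors (3.44-fold), although the second Myb probe set went the other way without passing. The G2 and mitosis list fell further (4 of 35, and 5 adjusted over the list alone; adjusted p = 0.000109), with Mki67 (2.63-fold) and Ccnb2 (at least 2.09-fold), and was lost at adjusted p = 0.069 with an estimated correlation. The histone list fell (2 of 15, and 2 adjusted over the list alone; adjusted p = 0.0244), with passing members Cenpa (2.33-fold) and H2az2 (1.9-fold), and was lost at adjusted p = 0.148 with an estimated correlation. Of the B lineage transcription factors 3 of 29 rose, among them Irf8 (2.91-fold), and 3 fell, among them Irf4 (3.28-fold; 3 higher and 4 lower adjusted over the list alone; list adjusted p = 0.18). Of the apoptosis list Mcl1 rose 2.36-fold and Bcl2l1, which encodes Bcl-x, fell 3.96-fold. Egr1, an immediate-early gene, rose 2.86-fold. Cxcr4, the receptor for the marrow chemokine Cxcl12, fell 4.11-fold. Ccnd2 was the 1 member of the G1 cyclin list to change, and that list had a median of −0.09 against a mean of 0.44 (adjusted p = 0.422).

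With the batch as a block 249 probe sets changed between immature and small pre-BII cells, 48 within sorts 1 to 3 and 121 within sorts 8 to 11. Of these 121, 96.7% went the same way within sorts 1 to 3, against 55.2% of all tested probe sets. List medians with the block, within sorts 1 to 3 and within sorts 8 to 11 were 1.61, 1.32 and 1.82 for MHC class II, 1.01, 0.97 and 0.94 for mature B cell genes, −0.85, −0.83 and −0.87 for V(D)J recombination, −0.85, −0.27 and −0.74 for early progenitor genes, 0.32, 0.23 and 0.47 for receptor signalling, 0.30, 0.53 and 0.21 for MHC class I, −0.36, −0.09 and −0.43 for G2 and mitosis, and −0.17, −0.04 and −0.10 for histones. Within sorts 1 to 3 the calls of early progenitor genes (adjusted p = 0.142), receptor signalling (0.187), MHC class I (0.0507), G2 and mitosis (0.185) and histones (0.319) were not reached. With values raised to the noise limit these 8 medians were 1.56, 0.34, −0.97, −0.58, 0.33, 0.38, −0.11 and −0.34. In the values as deposited 75 probe sets changed. Leaving out single preparations ended the call of Cxcr4 in 8 of 26 fits (adjusted p up to 0.148), H2-Q1 in 6 (0.0774), Psmb8 in 5 (0.102), Bcl2l1 in 3 (0.0602), Aqp4 in 3 (0.0612), the histone list in 3 (0.0996), Irf4 in 2 (0.0555), H2az2 in 2 (0.063) and the MHC class I list in 2 (0.0663), and with sort number, which paired these preparations, as a replicate block Cnp was not called.

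**Figure D3:**
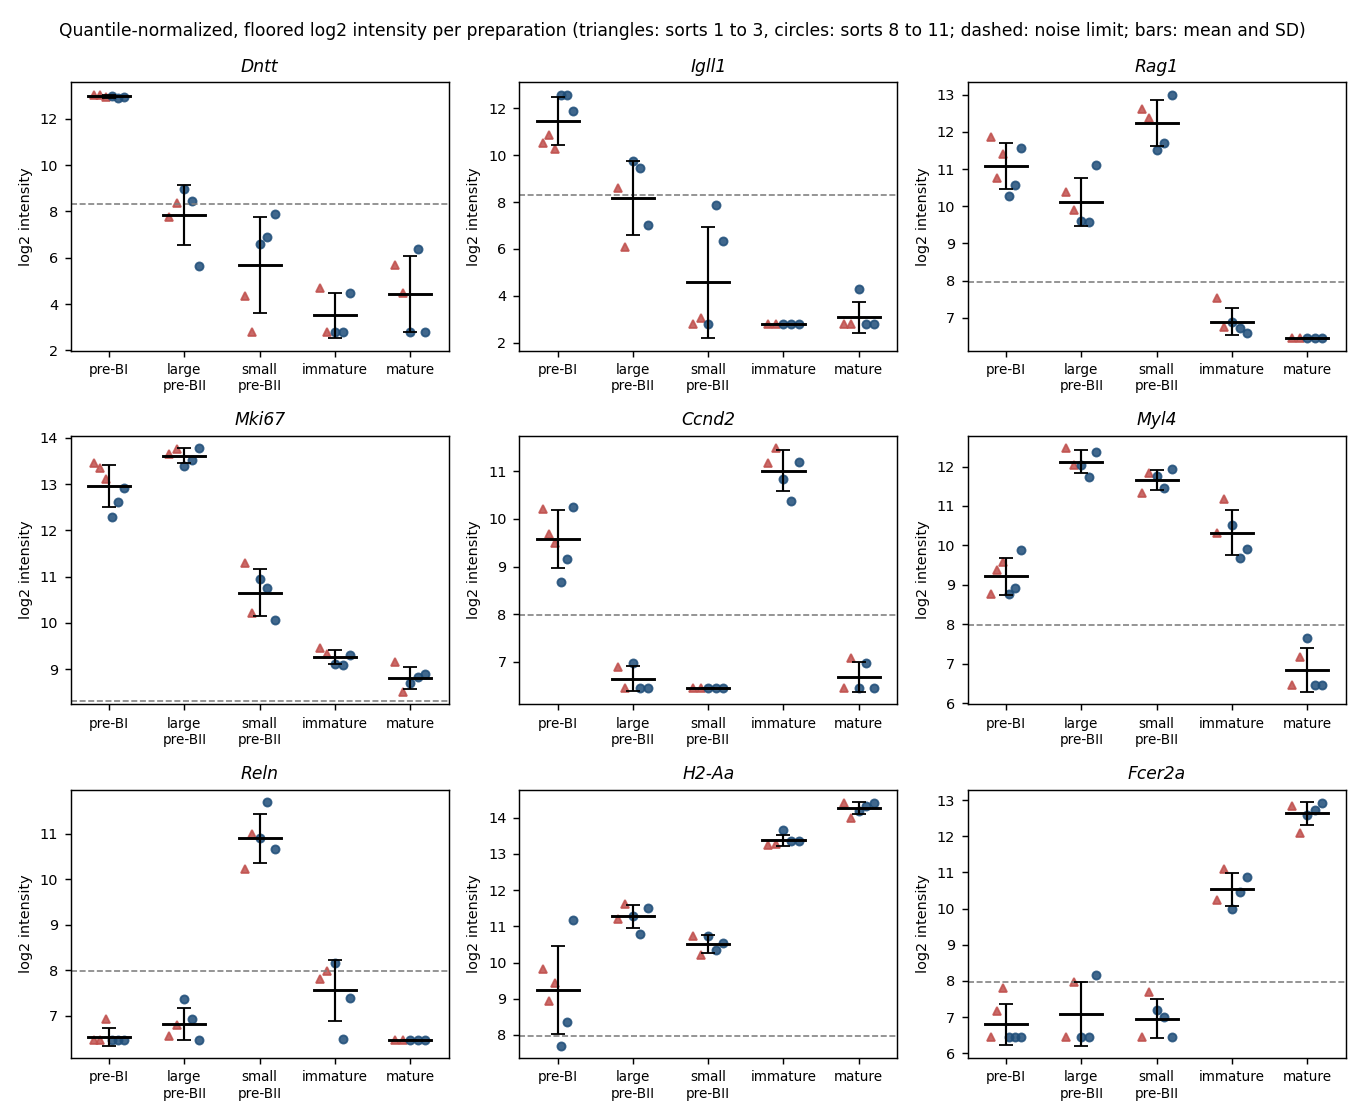
Quantile-normalised log2 intensity (vertical axis) of 9 genes in each of the 26 preparations by population (horizontal axis), with the brightest probe set of each gene. Triangles are sorts 1 to 3, circles sorts 8 to 11, bars are means with SD and the dashed line is the noise limit, under which values have no order. Ccnd2 lies above the limit in pre-BI and immature cells, and Reln in all small pre-BII preparations and 2 immature ones.

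Mature B cells were compared with immature B cells on 5 preparations each. Gimap4, a GTPase gene of lymphocytes, rose at least 14.6-fold (log2 difference 3.87 ± 0.09 SE, adjusted p = 4.59e-12), and H2-Aa rose 5.73-fold by one probe set (2.52 ± 0.19, adjusted p = 5.29e-05). The brighter H2-Aa probe set given for the earlier comparisons did not pass (0.89, adjusted p = 0.474). Fcer2a rose 4.3-fold (2.10 ± 0.25, adjusted p = 0.00108). Vpreb3, a surrogate light chain family gene, fell 13-fold (−3.69 ± 0.57, adjusted p = 4.28e-06), Cd93, the antigen that marks immature B cells, 8.5-fold (−3.09 ± 0.29, adjusted p = 7.31e-09), and Ccnd2 at least 8.23-fold (−3.04 ± 0.19, adjusted p = 1.21e-10). In all 139 probe sets changed, 63 higher and 76 lower.

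Other leading rises were Rflnb (at least 4.75-fold), Stat4 (at least 5-fold), Cr2, which encodes the complement receptor CD21 (at least 1.85-fold), Pacs1 (3.85-fold), Ms4a4c (at least 2.9-fold) and Fxyd5 (at least 2.11-fold). Other leading falls were Emid1 (10.7-fold), Myl4 (at least 5.09-fold), Myb (9.27-fold) and Zfpm1, a cofactor of GATA proteins (at least 3.22-fold). Cfp fell with both populations under the noise limit. The MHC class II list rose (4 of 10, and 7 adjusted over the list alone; adjusted p = 2.11e-10, and 0.000363 with an estimated correlation), with Ciita, its transcriptional coactivator (at least 1.05-fold), H2-Ob (3.81-fold), H2-DMb1 (3.92-fold) and H2-Oa (3.13-fold). Of the mature B cell list 5 of 23 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.000736, and 0.0237 with an estimated correlation). Cd55 (4.96-fold), Fcer2a, Itgb7 (4-fold) and Bcl2, an inhibitor of apoptosis (at least 1.98-fold), were among the rises, and the fall, named after its value was seen, was Cd1d1.

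The early progenitor list fell (5 of 20, and 5 adjusted over the list alone; adjusted p = 4.1e-06, and 0.000363 with an estimated correlation), and its passing members were Myb, Cd93, Vpreb3, Cd24a, the heat-stable antigen (1.84-fold), and Ly6d, named after its value was seen. The G1 cyclin list fell, with Ccnd2 the 1 member that passed (1 of 11, and 2 adjusted over the list alone; adjusted p = 0.0205, and 0.0481 with an estimated correlation). Iglc1 fell 3.57-fold and Cd72, an inhibitory coreceptor, 2.54-fold. A rise of the ribosomal protein list (0 of 43, and 0 adjusted over the list alone; median 0.27, adjusted p = 6.11e-05) was lost at adjusted p = 0.0988 with an estimated correlation. A fall of the oxidative phosphorylation list (0 of 56, and 0 adjusted over the list alone; median −0.29, adjusted p = 0.000284) was lost at adjusted p = 0.148 with an estimated correlation, and one of the proteasome list (2 of 31, Psmd8 and Psmd14; 2 adjusted over the list alone; median −0.28, adjusted p = 0.0113) at adjusted p = 0.135 with an estimated correlation.

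With the batch as a block 155 probe sets changed between mature and immature cells, 13 within sorts 1 to 3 and 63 within sorts 8 to 11. Of these 63, 98.4% went the same way within sorts 1 to 3, against 54.1% of all tested probe sets. List medians with the block, within sorts 1 to 3 and within sorts 8 to 11 were 1.62, 1.74 and 1.54 for MHC class II, 0.23, 0.43 and 0.39 for mature B cell genes, −0.24, −0.55 and −0.30 for early progenitor genes, −0.58, −0.54 and 0.00 for G1 cyclins, 0.27, 0.32 and 0.28 for ribosomal proteins, −0.29, −0.32 and −0.24 for oxidative phosphorylation, and −0.28, −0.16 and −0.32 for the proteasome. The G1 cyclin call was not reached within sorts 8 to 11 (adjusted p = 0.163) nor with sort number, which paired these preparations, as a replicate block (0.0665), and those of mature B cell genes (0.09) and the proteasome (0.0714) were not reached within sorts 1 to 3. With values raised to the noise limit these 7 medians were 1.77, 0.79, −0.38, −0.03, 0.29, −0.29 and −0.19. In the values as deposited 47 probe sets changed. Leaving out single preparations ended the call of H2-Oa in 18 of 26 fits (adjusted p up to 0.146), Cfp in 7 (0.107), Cd72 in 6 (0.1), Cr2 in 5 (0.0998), Psmd14 in 5 (0.14) and the proteasome list in 1 (0.0549, without immature B sort 2), and with the replicate block Cfp was not called.

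The ends of the series, mature B cells and pre-BI cells, were compared on 5 and 6 preparations. Among MHC class II genes H2-Eb1 rose 46.1-fold (log2 difference 5.53 ± 0.07 SE, adjusted p = 1.12e-06), H2-Aa 31.9-fold by the probe set taken for mature against immature cells (5.0 ± 0.03, adjusted p = 3.41e-12) and 31.7-fold by the brighter one taken for the earlier comparisons, H2-Ab1 30.2-fold (4.92 ± 0.17, adjusted p = 1.22e-05) and H2-DMa at least 11.1-fold. Of the MHC class II list 10 of 10 genes rose (10 adjusted over the list alone). Fcer2a rose at least 25.3-fold, Cd2 at least 6.35-fold, Capg at least 3.17-fold and Cr2 at least 1.85-fold by one probe set. The other Cr2 probe set, under the noise limit in mature cells, did not pass (−0.42, adjusted p = 0.59). Dntt fell at least 25.2-fold (−4.65 ± 0.03, adjusted p = 8.25e-09), Ptgr1 at least 21.8-fold, Hmgb2 at least 14.9-fold and Igll1 at least 8.8-fold. The other leading falls were Eng (at least 3.33-fold), Ppp1r14b (at least 3.96-fold), Stmn1, a regulator of microtubules (at least 5.18-fold), and Lef1 (at least 2.24-fold). In all 1086 probe sets changed, 483 higher and 603 lower.

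Camera was not run over this comparison as part of the adjusted family, so its lists are described by their counts. Of the early progenitor list 12 of 20 fell and 1 rose (14 and 1 adjusted over the list alone), with Myb (20-fold) and Cd93 (16.9-fold), and of the V(D)J recombination list 5 of 9 fell (5 adjusted over the list alone), with Rag1 (at least 8.6-fold). The DNA replication list had 23 of 35 lower (29 adjusted over the list alone) and the G2 and mitosis list 28 of 35 (30 adjusted over the list alone), with Mki67 (17.2-fold) and Prc1 (at least 5.21-fold). Of the oxidative phosphorylation list 18 of 56 fell (27 adjusted over the list alone), with Ndufv2 (2.44-fold) and Cox5a (1.99-fold). Of the ribosome biogenesis list 9 of 28 fell (13 adjusted over the list alone), with Ran (2.38-fold) and Eif4a1 (2.51-fold). The mature B cell list had 16 of 23 higher (17 higher and 1 lower adjusted over the list alone), and the receptor signalling list 9 of 20 higher and 1 lower (12 and 1 adjusted over the list alone), with Cd22 (at least 13.9-fold) and Blk (4.06-fold). Of the immunoglobulin list 5 of 12 rose (6 adjusted over the list alone), among them Ighd, the delta heavy chain gene (at least 2.74-fold). Kit fell (adjusted p = 0.000351) from its low level. With the batch as a block 1207 probe sets changed, 360 within sorts 1 to 3 and 842 within sorts 8 to 11. Of these 842, 94.5% went the same way within sorts 1 to 3, against 61.6% of all tested probe sets. In the values as deposited the count was 498.

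The remaining lists had no camera call in the 4 consecutive comparisons. Their lowest adjusted p-values were 0.18 for B lineage transcription factors (immature against small pre-BII), 0.0538 for homing and adhesion (small against large pre-BII, with 2 of 20 higher and 3 adjusted over the list alone), 0.0712 for apoptosis, 0.18 for immediate-early and stress genes (small against large pre-BII, 3 higher and 2 lower of 18, and 8 and 3 adjusted over the list alone) and 0.0538 for interferon-associated genes (immature against small pre-BII, 0 of 20, and 1 adjusted over the list alone). Fry passed some of these lists. Between small and large pre-BII cells these were homing and adhesion (adjusted p = 0.000236), apoptosis (0.000439) and interferon-associated genes (0.00338), all higher. Median, mean and camera test had the same sign in each of the 29 list calls. They differed in sign, outside the calls, for 6 lists between large pre-BII and pre-BI cells (receptor signalling, MHC class II, G1 cyclins, immediate-early, erythroid and plasma cell genes). They also did for V(D)J recombination, T and NK cell and stromal genes between small and large pre-BII cells, and for G1 cyclins between immature and small pre-BII cells. Between mature and immature cells they differed for V(D)J recombination, MHC class I, G2 and mitosis, histone, glycolysis, apoptosis, interferon-associated, megakaryocyte and stromal genes.

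Lists of other cell types were tested to see what else the sorted preparations held. None was called by camera. Their lowest adjusted p was 0.0729 for granulocyte markers (large pre-BII against pre-BI, 0 of 14 changed and 3 lower adjusted over the list alone). It was 0.0705 for plasma cell genes, 0.133 for erythroid markers and 0.15 for monocyte and macrophage markers (large pre-BII against pre-BI, median −0.45). For T and NK cell, megakaryocyte and mast cell, and stromal and endothelial markers it was 0.517. Fry passed falls of monocyte and macrophage (adjusted p = 0.0187) and granulocyte markers (0.0431) between large pre-BII and pre-BI cells. It also passed falls of erythroid markers between small and large pre-BII (0.026) and of plasma cell genes between mature and immature cells (0.0356). Abundant transcripts of other marrow cells were bright in all 5 populations. Hba-a1, an alpha globin gene, lay between 8070 in small pre-BII and 11100 in mature cells, and Hbb-b2, a beta globin gene, between 2680 and 5620 in the same 2 populations. The granulocyte genes Lyz2 and Ngp were highest in pre-BI cells, at 5300 and 3760, and Lyz2 was lowest in small pre-BII cells, at 1730. Their list had a median of −0.39 between large pre-BII and pre-BI cells, beside the falls of early progenitor and ribosome biogenesis genes. The list median was −0.03 between small and large pre-BII cells. It was 0.54 between immature and small pre-BII and 0.35 between mature and immature cells, beside the rises of MHC class II and mature B cell genes. The median Gapdh 3' to 5' ratio on the first set, a sign of RNA integrity, was 3.99 in pre-BI, 4.83 in large pre-BII, 5.63 in small pre-BII, 5.49 in immature and 2.85 in mature preparations, with the highest single ratios, 17.4 and 13.4, in small pre-BII sort 8 and immature sort 2. On the b set the medians had another order, 4.74, 3.38, 3.53, 5.06 and 4.24 in the same populations.

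**Figure D4:**
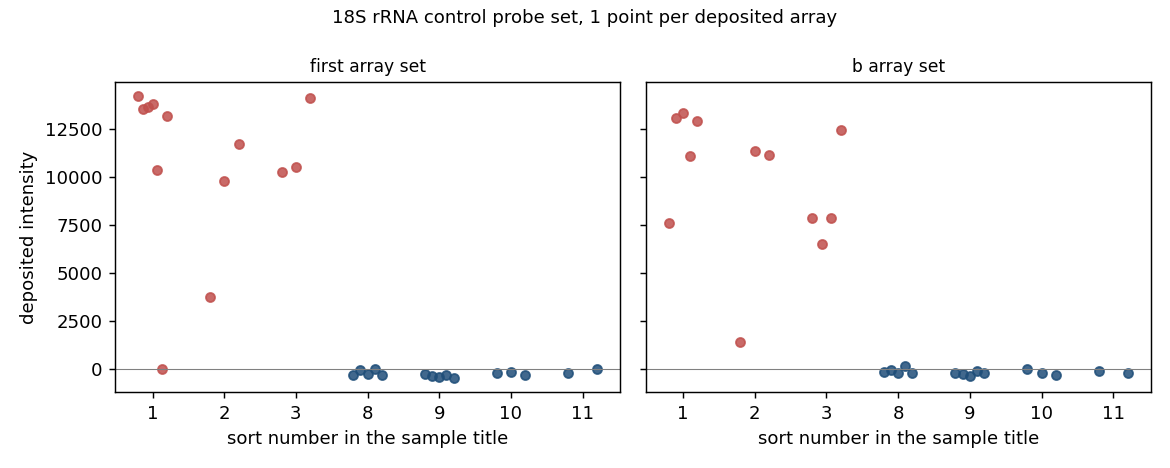
Deposited intensity (vertical axis) of an 18S ribosomal RNA control probe set on each array by sort number (horizontal axis), for the first array set (left) and the b set (right). Arrays of sorts 1 to 3 lay at 3741 to 14192 on the first set and 1447 to 13320 on the b set, and those of sorts 8 to 11 at −452 to 28 and −336 to 194; the 1 low point at sort 1 on the first set is the array identical to mature B sort 11.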

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

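The tests of Prm1, of pre-BI sort 10, of an additive batch shift and of the batch as the whole cause were chosen, and their criteria set, only after the results had been seen; that of a batch difference was set before its value was known. Dixon's criterion for a sample far from the others of its group singled out 6 of 130 groups, where chance gives about 1 in 20, or 6.5. The list score of MHC class II genes in pre-BI sort 10 was −0.267 against −1.971 to −1.529 in the other pre-BI preparations. That of mature B cell genes in small pre-BII sort 3 was −0.034 against −0.522 to −0.401, and that of histone genes in small pre-BII sort 1 was 0.192 against −0.218 to −0.137. The Gapdh 3' to 5' ratio of immature sort 2 on the b set was 17.7 against 2.75 to 5.34. Il2ra read 6.87 on the log2 scale in mature sort 1 against 6.45 by one probe set, and 6.85 in immature sort 1 against 2.78 to 3.14 by the other, all under the noise limit. The number of such samples is what chance gives.

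A signal in control probe sets outside the comparisons was the 18S ribosomal RNA: its median was 12447 on the first set and 11135 on the b set in sorts 1 to 3, with −452 to 28 and −336 to 194 in sorts 8 to 11. The median Gapdh 3' to 5' ratio also differed between these batches, 5.62 against 3.23 on the first set and 6.16 against 3.23 on the b set. No biological explanation was tested, since both batches hold all 5 populations. If a batch difference lay behind the calls, 60% or fewer of the probe sets called within sorts 8 to 11 would go the same way in sorts 1 to 3 in some comparison, and otherwise 90% or more in each. The lowest was 85.3%, for large pre-BII against pre-BI, and the others were 94.1 to 98.4%. Of all tested probe sets 53.8 to 61.6% did. By this test it stayed open whether the batch lay behind part of the calls. The batch as the whole cause was argued against, since 63 to 842 probe sets were called within sorts 8 to 11 alone. For an additive shift the counts with the batch as a block were at least 1.07 times those without, but sorts 1 to 3 made up 50% of pre-BI and 40% of each other population, so a block could hardly lower the counts. This test of counts decided nothing, although its result had first been counted against such a shift. Populations other than pre-BI held equal shares of sorts 1 to 3, so an additive shift could not part them. With the block, which removes such a shift, 194 of 199 calls stayed for large pre-BII against pre-BI. For mature against pre-BI 1085 of 1086 stayed. These values argue against an additive shift behind those calls. Population differences that depend on the batch stayed open.

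Prm1, a sperm protamine gene, rose in small pre-BII cells (median 1010, against 90.8 in large pre-BII and 27.2 in immature cells). A transcript shared with Socs1, its neighbour in the gene order Socs1, Tnp2, Prm3, Prm2, Prm1 on chromosome 16, would make both move alike. Socs1, chosen after its values were seen, had medians of 1040 in small pre-BII, 566 in large pre-BII and 79 in immature cells, and Prm1 rose by 1.51 more than Socs1 on the log2 scale (95% interval −0.02 to 3.04). The interval includes a difference of 2-fold, and no large pre-BII preparation exceeded the noise limit for Prm1, so its rise is a bound. The interval also treats the 2 genes as read on separate preparations, although both were read on the same ones. It therefore left this open. Socs1 exceeded the limit in 5 large pre-BII preparations, where Prm1 did in 0. In small pre-BII Socs1 did in 3 and Prm1 in 5. Prm2, which lies between them, did in 0 small pre-BII preparations (median −3.70). The criterion had first been a difference over 2 SE, which 1.51 ± 0.671 would have met, counting against a shared transcript; it was replaced by the interval after the value had been seen. Germ cell transcripts expressed together were argued against, since 1 of 9 others, Pgk2, exceeded the noise limit.

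Pre-BI sort 10 was weighed for the MHC class II score. RNA of mature B cells at the share read from H2-Aa (11.6%) would carry other mature transcripts, of which 2 were informative. Cd22 read 7.83 on the log2 scale where 8.67 was needed, within an allowance of 2-fold but under the noise limit of 7.97, and Fcer2a read 6.45 where 9.53 was needed (50% within the allowance). Fcer2a thus read under the limit where a level above it was needed, and Cd22 was counted only through the allowance. With 2 genes that differ in this way, in a single preparation, this stayed open. RNA of macrophages or monocytes stayed open too: that list score was 0.145, within −0.359 to 0.2 in the other pre-BI preparations, but no value says how far such RNA would raise it. A score within that range had first been counted against it. Both tests were set up once the values of this preparation were known. This preparation lay above all other pre-BI preparations for 12 of 29 lists. Among them were mature B cell genes (−0.649 against −1.207 to −0.838), T and NK cell genes (1.061 against −0.282 to 0.201, with Ccl5 at 2200 against 69.6 to 336), homing and adhesion (0.081 against −0.737 to −0.111) and stromal markers (0.289 against −0.583 to −0.126). A test of granulocyte RNA in pre-BI cells had been run first and was replaced by this one: of 7 abundant granulocyte genes 6 were highest in pre-BI cells (Lcn2, S100a9, Camp, Ngp, Lyz2 and Chil3) and S100a8 was not.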

How the results depend on the processing

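The batch, noise limit, identical array and Gapdh alternatives, 7 of 50, were chosen after seeing the data. No called gene value or list shift reversed in the settings it was run in, although 2 of the 1086 probe sets changed between mature and pre-BI cells had the other sign within sorts 1 to 3.

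Leaving out each of the 26 preparations gave 162 to 225 changed probe sets for large pre-BII against pre-BI, 489 to 584 for small against large pre-BII, 189 to 235 for immature against small pre-BII, 113 to 151 for mature against immature and 951 to 1144 for mature against pre-BI, 1391 to 1560 in the F test, and 27 to 34 list calls.

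Counts moved by more than 1.5 times in these settings, in the order of those comparisons. The values as deposited gave 48, 201, 75, 47 and 498, and 700 in the F test; of the 201, 42 were higher and 159 lower. Array scale differed over 4-fold there, but the cause was not tested. Sorts 1 to 3 alone gave 8, 117, 48, 13 and 360, and 391 in the F test, and sorts 8 to 11 alone 75, 353, 121 and 63 in the consecutive comparisons; both hold fewer samples. For large pre-BII against pre-BI a floor at the 25th percentile gave 129, one at the 60th 302, and sort number as a replicate block 328, where the numbers pair; the cause was not tested. The estimated inter-gene correlation gave 19 list calls in place of 29. For the lists that lost a call the estimate lay above the preset 0.01, from 0.0204 (immunoglobulin genes) to 0.0963 (ribosomal proteins).

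Of 251 called gene values, 90 kept their side of the threshold within sorts 1 to 3, 169 within sorts 8 to 11, 207 in fits of 2 populations and 209 with the floor at the 25th percentile; of 29 list calls, 19, 27, 29 and 27 did. Further, 240 of the gene values kept their side of the threshold with trimmed-mean scaling, 227 with the 75th percentile, 139 as deposited, 250 with the batch as a block, 245 with the replicate block and 230 without the 2 preparations of highest Gapdh ratio. Of the list calls, 28, 27, 25, 29, 27 and 27 did; without those 2 preparations MHC class I (immature against small pre-BII) and the proteasome (mature against immature) were lost. The immunoglobulin list (small against large pre-BII) was lost with the replicate block (adjusted p = 0.0813).

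Lists under the random block, and in the settings that fit each table apart, were not run. Signal over background limits what can be measured: 40% of values on the first set and 20.1% on the b set exceeded the noise limit, so dim genes such as Il2ra were not measurable.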

Other observations

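The explanation tests in this part were fixed in kind beforehand, except the estimated-correlation assignments and the shuffled deviations, which were added after the preset list result had been seen.

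Several genes were high at 1 or 2 separate stages. Ccnd2 averaged 764 in pre-BI, 99.9 in large pre-BII, 87.6 in small pre-BII, 2070 in immature and 103 in mature cells. Reln averaged 1910 in small pre-BII cells and 189 or less elsewhere. Emid1 averaged 4410 in immature cells against 1360 or less elsewhere.

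Other assignments of the preparations to populations were tried, 100 in each case with the real one included. For each count of changed probe sets 1 of 100 unpaired splits, the real one, reached the real value, and by this rank chance was argued against. The real count was 199 against 108 in the highest other for large pre-BII against pre-BI, and 570 against 34 for small against large pre-BII. It was 226 against 46 for immature against small pre-BII and 139 against 9 for mature against immature. For mature against pre-BI it was 1086 against 793, and in the F test 1524 against 5. Other splits leave population differences in the residuals, which can lower their counts, so these margins do not measure the strength of the evidence. These splits ignore the pairing of sort numbers. Among splits that part every pair, 1 of 32 reached the real value for large pre-BII against pre-BI (199 against 65) and 1 of 24 for immature against small pre-BII (226 against 2). For mature against immature the 16 such splits are too few for a share under 0.05 (139 against 0). Such splits were not run for small against large pre-BII or mature against pre-BI, where a pairing is not excluded. For list calls at the preset correlation chance was not excluded: 12 of 100 reached the real 29, and the highest other had 46. With an estimated correlation 1 of 100 reached the real 19 calls, and the highest other had 1. This cannot exclude chance for those calls, since other assignments leave the population differences in the residuals that give the correlation. With deviations shuffled between preparations, which leaves no population difference, 0 of 99 draws reached 29, and the highest had 8. Yet 44 of the 99 draws had calls, so a single call at the preset correlation may be false.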
